A study of Mus musculus with 2 samples.

How the data were processed

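H3K9me3, the trimethylation of lysine 9 of histone H3 that marks heterochromatin, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in neural tube dissected from mouse embryos of the B6NCrl strain at embryonic day 15.5. The labels give 1 group of 2 biological replicates. Replicate 1 was a pool of tissue from 78 embryos and replicate 2 a pool from 62 embryos, each of both sexes. Replicate 1 combined technical replicates 1 and 2, and replicate 2 held a single technical replicate. The design has no second tissue, age or mark, so every comparison was between the replicates, between parts of the genome, or between gene lists.

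The authors deposited 4 peak lists on the mm10 assembly, per the labels and the notes that accompany the lists. One list was called on each replicate, one on both replicates together (the pooled list), and a replicated list was derived from the other 3. A control library went into the calls, per the same notes. The peak caller, its threshold and the rule that made a peak replicated are not given in the sources used here. In the deposited narrowPeak format the authors' signal value is 1 number per peak, the enrichment of the peak as their caller gave it, and the authors' −log10 q value is the significance of the peak after correction. Both belong to the peak and its list, and were used here mainly to describe, rank or filter peaks within a list. The signal value was also compared by rank between the replicates' lists, and tested between scaffold and chromosome peaks. The lists hold no read counts, so the depth of the libraries is unknown, no counting interval of the signal can be given, and absence of a peak does not show absence of the mark. The lists also hold only peaks that passed the authors' threshold, and how reads that match several places were treated is not given in the sources used here. Where such reads are discarded, the mark over young repeats is missed.

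Each of the 13495 replicated peaks was an identical row of the pooled list. No peak ended beyond its chromosome in the GRCm38.p6 reference, which has the coordinates of mm10. Analyses used the 21 assembled nuclear chromosomes, which held 13247 of the replicated peaks; peaks on unplaced and unlocalized scaffolds were kept only in the description of whole lists (numbers, widths, signal and q values) and in the test of the rule for the replicated list, and were examined apart. Gene models were those of GENCODE release M21, which the 55413 annotated genes came from, and bases in lower case in the reference copy were taken as masked repeats.

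The background for overlaps, features, gene lists and base composition was circular rotation. The 21 chromosomes without their unknown bases were laid end to end, and 1 of the peak lists was moved along this circle by the same random distance, which keeps the spacing of peaks and of genes. This is a permutation test of position. The main tests used 10000 rotations and the alternatives 2000, except for 10000 random lists matched on gene length, so that the smallest p was 0.0001 one-sided and 0.0002 two-sided in the main tests, and 0.001 two-sided in the alternatives with 2000 rotations. The random lists matched on gene length draw genes independently, so unlike rotation they take no account of the clustering of gene families. Base composition used 100 rotations, with a smallest two-sided p of 0.0198. Tests of features and of gene lists were two-sided with Benjamini-Hochberg adjustment over the 4 features or the 19 lists, and the overlap test was one-sided. P-values from rotations say how unusual a placement on the genome is for these peak lists; they carry no information on variation between animals, for which the 2 pools are the only replicates.

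A peak was counted as shared when the other replicate's peaks covered at least 50% of its length. Peak centres were assigned to promoters (1 kb either side of an annotated transcription start site, TSS), then exons, introns and intergenic sequence, in that order. These features came from annotated genes of every type, pseudogenes and noncoding genes included. A gene was counted as holding the mark when at least 1 bp of its body lay under a replicated peak. Dense regions were sought in windows of 1 Mb, and peaks no more than 5 kb apart were joined into domains. The alternatives set before the data were examined were overlap of 1 bp or of 50% of both peaks, a −log10 q of at least 2, the 10000 strongest peaks, the pooled list, each replicate's own list (which leaves the other replicate out), promoters of 2 kb, peak summits, gene windows of 2 kb either side of the TSS, at least 500 bp under peaks, random lists matched on gene length in 20 bins, windows of 500 kb, joining distances of 1, 10 and 20 kb, and 200 bp around summits. Chosen after the data were seen were overlap by rank in steps of 2000 peaks, a test of one rule for the replicated list, gene lists without the protocadherin region or without chromosome 7, and named genes with overlapping gene models passed over.

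The rule for naming genes was also set before the data were examined. It took the 25 protein-coding genes with the most base pairs under replicated peaks among genes that also held a peak of each replicate, up to 4 members per gene list with the strongest replicated peak by signal value, the 10 strongest replicated peaks, and the genes of the 10 densest windows as families. The 19 lists were zinc finger genes, olfactory receptors, vomeronasal receptors, clustered protocadherins, defensins, cytochrome P450 families 2 to 4, serpin clades A and B, keratin-associated proteins, the Rhox cluster, Hox genes, ribosomal protein genes, imprinted genes, germline genes, neural progenitor and patterning genes, neuronal genes, glial genes, genes of blood, vessel, muscle and mesenchyme, hepatocyte genes, and genes of H3K9 methylation and heterochromatin. Family members were found by symbol among protein-coding genes; the imprinted list also took noncoding genes. Of the 24 symbols of the last list 23 were annotated.

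The code was tested on simulated peaks before use. Planted sharing of 20.2% of 37895 peaks was recovered as 19.9%, a planted list of 200 genes was recovered at p = 0.001 in the rotation (permutation) test, and 1 of 40 random gene lists passed p under 0.05. With no planted sharing the observed overlap was 0.836 times the rotation mean. The random lists were genes scattered over the genome, so the rate of false calls for clustered families was not checked. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0, and matplotlib 3.10.9 for plots.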

Results

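H3K9me3 peaks in embryonic day 15.5 neural tube were examined in 1 group of 2 biological replicates, pools of 78 and 62 embryos. The replicated list held 13495 peaks that covered 7.69 Mb, and the pooled list from which they were taken held 72645 peaks over 22.8 Mb. Replicate 1 alone gave 38263 peaks and replicate 2 alone 48899 peaks. Replicated peaks had a median width of 466 bp and a median signal value, the enrichment given by the authors' caller, of 3.38, with an interquartile range of 3.08 to 3.85. The longest replicated peak spanned 10919 bp. Of the replicated peaks 83.9% had a −log10 q of at least 2, against 30.5% of the pooled peaks, from which they were taken with the same q. The depth of the libraries is unknown.

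Each replicate's most significant peaks were found in the other replicate's full list far more often than its weak ones. Of the 37895 peaks of replicate 1 on chromosomes, 21.1% were covered over at least 50% of their length by peaks of replicate 2, and 15.2% of the 48530 peaks of replicate 2 were covered in the same way by replicate 1. Rotated lists gave 0.485% and 0.369%, so that the observed sharing was 43.4-fold and 41.2-fold above background (one-sided rotation, a permutation test, p = 0.0001 for both, the smallest 10000 rotations can give). Among the 2000 peaks of highest −log10 q the share was 55.6% in replicate 1 (95% Wilson interval, 53.4% to 57.8%) and 53.5% in replicate 2 (51.3% to 55.6%). Among peaks ranked 34001 to 36000 it was 10.1% in replicate 1 (8.85% to 11.5%) and 8.0% in replicate 2 (6.89% to 9.27%). The Wilson intervals treat peaks as independent, and since peaks lie in clusters they are likely too narrow. With both lists limited to a −log10 q of at least 2 the shares were 21.2% and 17.8%, no lower than those of all peaks. With the 10000 strongest peaks of each by signal value they were 15.3% and 13.9%, below those of all peaks. Across the 7977 peaks of replicate 1 with a partner, the signal value of the strongest overlapping peak followed that of the peak itself only loosely, with a Spearman coefficient of 0.191 across peaks (bootstrap 95% interval, 0.170 to 0.214), where peaks are not independent replicates. With peaks of −log10 q of at least 2 in both lists the coefficient was 0.386.

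**Figure D1:**
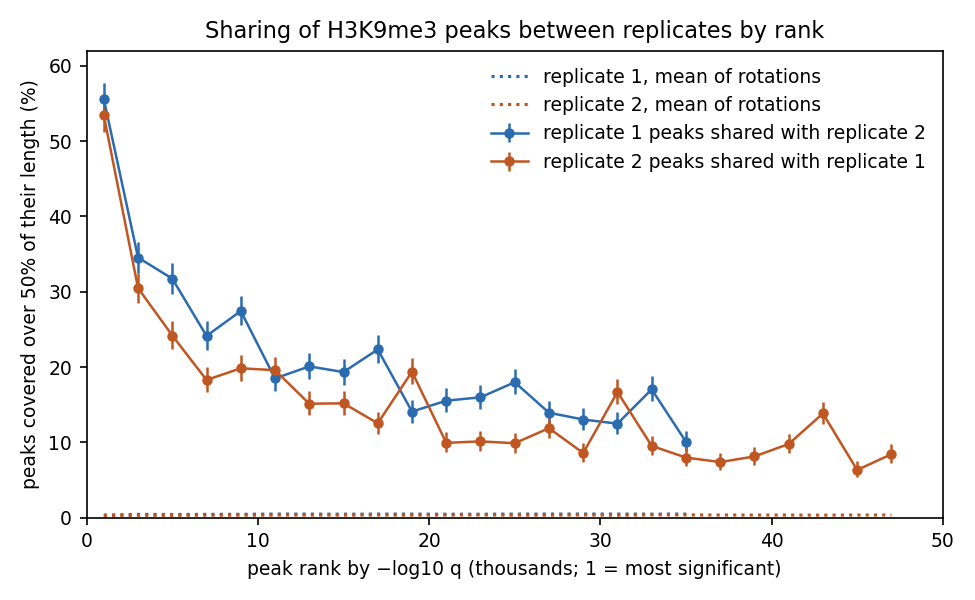
Share of each replicate's peaks covered over at least 50% of their length by the other replicate's peaks (y axis, percent) in steps of 2000 peaks by rank of −log10 q (x axis, in units of 1000 peaks). Bars are 95% Wilson intervals, which treat peaks as independent, and dotted lines the mean of 200 rotations. The share starts at 55.6% in replicate 1 and 53.5% in replicate 2 and lies far above the rotations at every step.

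The replicated list was derived from the replicates' lists, so that its coverage by them describes the authors' rule and does not test agreement. Of the 13247 replicated peaks on chromosomes, 68.4% were covered over at least 50% of their length by peaks of replicate 1 and 71.3% by peaks of replicate 2. For 47.5% this held in both replicates at once, for 20.9% only in replicate 1 and for 23.8% only in replicate 2, and 1032 peaks (7.79%) reached it in neither. With 1 bp of overlap 80.5% were met in both replicates and 55 peaks in neither. A rule that asked for 50% of either the pooled or the replicate peak in both replicates picked 10802 pooled peaks, all of them on the replicated list, which is 80.0% of it.

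Chromosomes 7, 17 and 4 held replicated peaks most densely, and the sex chromosomes least. Chromosome 7 had 10006 bp of replicated peaks per Mb, 3.55 times the genome-wide density, chromosome 17 had 2.44 times and chromosome 4 had 1.76 times. These ratios were lower in the replicates' own lists, at 2.77 and 2.54 for chromosome 7, 2.12 and 1.96 for chromosome 17, and 1.47 and 1.41 for chromosome 4, in replicates 1 and 2. Chromosome 18 stood at 1.61 times the genome-wide density with replicated peaks and chromosome 13 at 1.36 times, while chromosomes 14 and 15 were at 0.392 and 0.419 times. Most of the chromosome 18 value came from a single locus. The protocadherin cluster described below held 3.48% of replicated-peak base pairs, of the 5.32% that lay on chromosome 18. The X chromosome had 0.233 times the genome-wide density, with 194 replicated peaks. In the replicates' own lists the X stood at 0.431 in replicate 1 and 0.635 in replicate 2, a wider gap between replicates, relative to the values, than on the other chromosomes named here. The Y chromosome held 12 replicated peaks, and 96.3% of its known bases were masked as repeats in the reference copy.

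**Figure D2:**
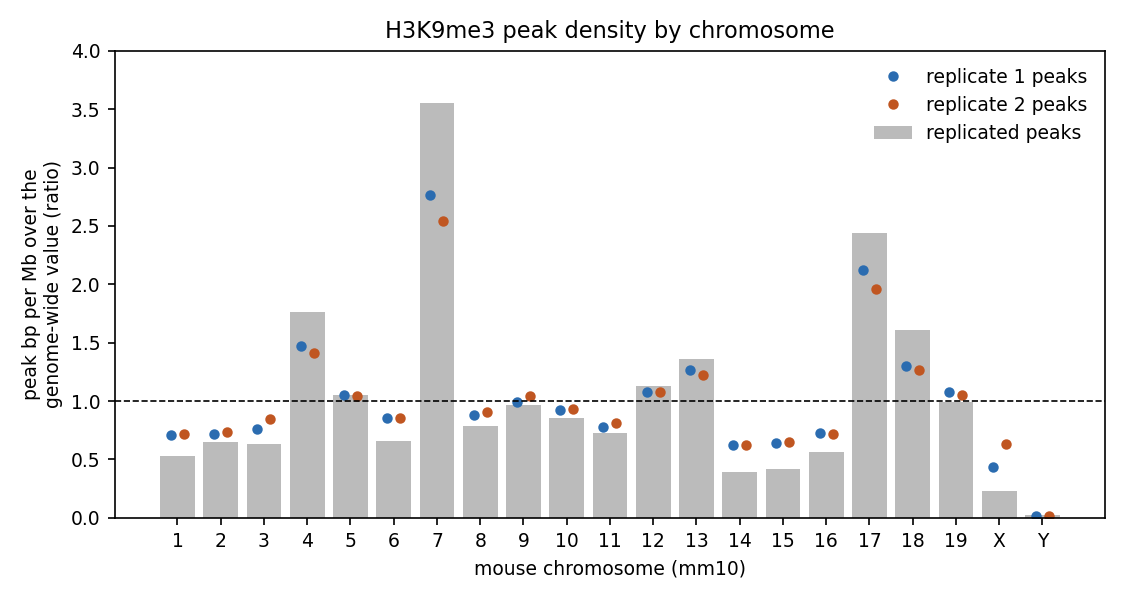
Peak base pairs per Mb of each mouse chromosome (x axis) over the genome-wide value (y axis, ratio), as grey bars for replicated peaks and points for each replicate's own list; the dashed line marks 1. Chromosome 7 reaches 3.55 with replicated peaks, 2.77 in replicate 1 and 2.54 in replicate 2.

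Exons and promoters of annotated genes of every type held more peak centres than rotation placed there, and introns fewer. Exons held 5.80% of the 13247 centres against 3.19% under rotation (1.82-fold, adjusted permutation p = 0.0004, two-sided rotation test), and introns 27.9% against 38.3% (0.729-fold, adjusted permutation p = 0.0004). Promoters held 8.48% against 6.06% (1.4-fold, adjusted permutation p = 0.0064). Intergenic sequence held 57.8% of the centres against 52.4%, which did not pass (1.10-fold, adjusted permutation p = 0.0578). It did pass without replicate 1 (1.14-fold, adjusted permutation p = 0.00133), without replicate 2 (1.13-fold, adjusted permutation p = 0.00133) and in the pooled list (1.17-fold, adjusted permutation p = 0.002). The promoter excess was not found in the pooled list (1.01-fold, adjusted permutation p = 0.856), in replicate 1's own list (1.11-fold, adjusted permutation p = 0.061) or in replicate 2's own list (1.02-fold, adjusted permutation p = 0.597).

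Of the 19 gene lists, 5 held replicated peaks in more of their members than rotation gave, and 0 held them in fewer, at an adjusted p under 0.05. At an unadjusted p under 0.05, 6 lists had more, the germline list being the sixth, and 0 had fewer. In all, 1760 of 21938 protein-coding genes (8.02%) had a replicated peak in the gene body. The 5 lists were clustered protocadherins, vomeronasal receptors, imprinted genes, zinc finger genes and cytochrome P450 families 2 to 4.

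Nearly all clustered protocadherins, cell adhesion proteins of which each neuron makes its own combination, held a replicated peak. One lay in 53 of 57 genes (93.0% against 15.5% under rotation, 6.01-fold, adjusted permutation p = 0.0019, two-sided rotation test). The Pcdha models overlap and end together, as do the Pcdhg models, so that a single peak can count for several genes. The groups taken apart are given with the gene families below. The fold was 2.11 without replicate 1 (adjusted permutation p = 0.0076), 2.40 without replicate 2 (0.00475), 1.88 in the pooled list (0.0332), 10.1 with at least 500 bp under peaks (0.00475) and 58.7 within 2 kb of the TSS (0.00475). The 4 without one were Pcdhac2, Pcdhgc3, Pcdhgc4 and Pcdhgc5, named here because they complete the count. Over the cluster, chromosome 18 from 36910184 to 37861873, 332 replicated peaks covered 259 kb or 27.3% of the sequence, and the replicates' own lists covered 203 kb in replicate 1 and 225 kb in replicate 2. The longest domain, 120 kb from 37656245 to 37775774, joined 76 peaks over the Pcdhga and Pcdhgb genes and was covered over 75.1% of its length. The Pcdhg gene models share their 3' end and overlap, so that Pcdhga1 (87.9 kb under peaks), Pcdhga2 (84.5 kb), Pcdhga3 (80.8 kb) and Pcdhgb1 (76.0 kb) were largely counted from the same peaks. The strongest peak of all 4 was the same, at 37714845 to 37717710, in exonic sequence 1.51 kb past the Pcdhga7 TSS, with a signal value of 6.83. Of the 25 protein-coding genes with the most base pairs under replicated peaks, 23 lay in this cluster, among them the overlapping models Gm42416 (239 kb), Gm37013 (232 kb) and Gm37388 (229 kb).

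**Figure D3:**
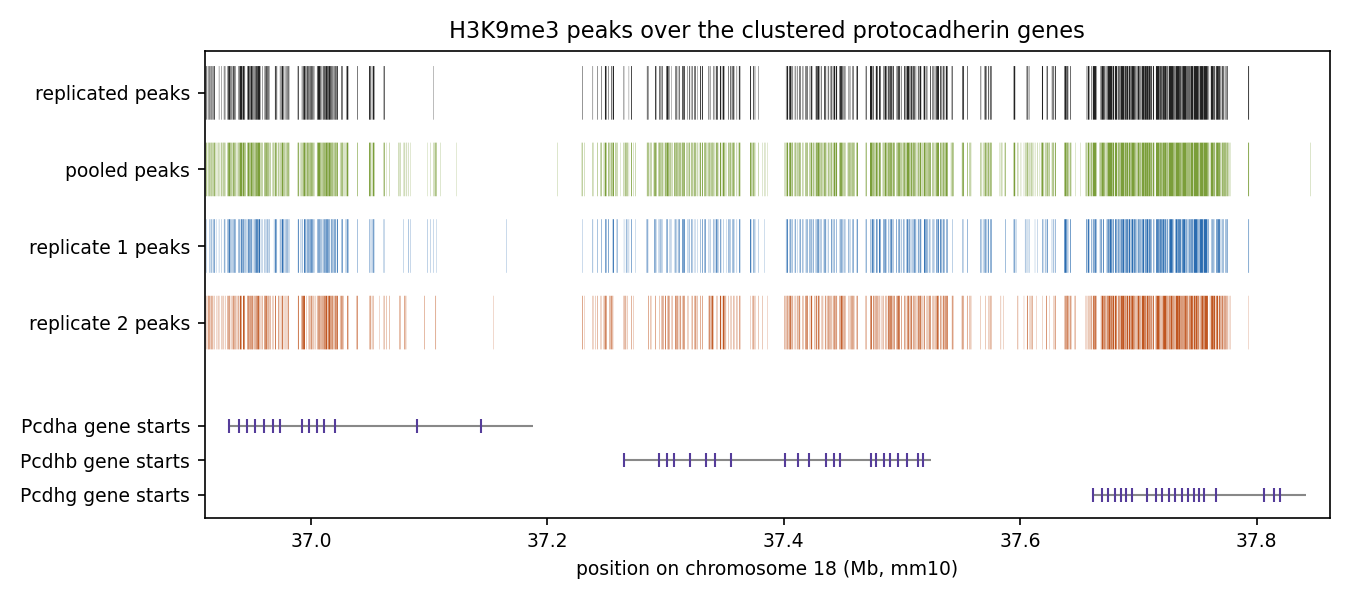
Peaks of the 4 lists (rows of bars) over the clustered protocadherin genes on chromosome 18 (x axis, Mb, mm10), with ticks at the starts of the Pcdha, Pcdhb and Pcdhg genes and a grey line over each group's extent. Peaks narrower than a pixel show paler. Replicated peaks cover 27.3% of the region and are packed most closely over the starts of the Pcdhg genes.

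Zinc finger genes, most of which code transcription factors with arrays of C2H2 fingers, held the mark in 136 of 423 members (32.2% against 6.75%, 4.76-fold, adjusted permutation p = 0.00127, two-sided rotation test). The strongest peaks lay in Zfp110 (signal value 7.0, intronic), Zfp68 (6.83, exonic), Zfp180 (6.79, exonic) and Zfp873 (6.65, intronic). Peaks covered 82.3% of the Zfp110 gene body on chromosome 7 from 12834761 to 12850577, and 81.9% of that of Zfp873 on chromosome 10 from 82048123 to 82064745. In replicate 1's own list Zfp110 had 9.66 kb under peaks and in replicate 2's 11.3 kb, and Zfp873 had 10.6 kb and 11.5 kb. Within 2 kb of the TSS only 12 of the 423 genes held a peak (1.68-fold, adjusted permutation p = 0.517). Over gene bodies the fold was 2.03 without replicate 1, 2.12 without replicate 2, 1.79 in the pooled list and 7.51 with at least 500 bp under peaks, each past the threshold.

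Vomeronasal receptors, which sense pheromones in the nose, held a replicated peak in 81 of 327 genes (24.8% against 4.22%, 5.86-fold, adjusted permutation p = 0.00127, two-sided rotation test). The strongest were in Vmn1r81 (signal value 5.43), Vmn2r16 (5.25), Vmn2r98 (5.08) and Vmn2r59 (4.90). The fold was 2.28 without replicate 1, 2.81 without replicate 2, 2.01 in the pooled list and 8.93 with at least 500 bp under peaks, each past the threshold. Among cytochrome P450 genes of families 2 to 4, enzymes of drug, steroid and fatty acid oxidation, 18 of 72 held one (25% against 6.44%, 3.88-fold, adjusted permutation p = 0.0122). Examples were Cyp2c38 with 3.24 kb under peaks, Cyp3a57 with 2.66 kb, Cyp3a44 with 1.30 kb and Cyp2b13 with 3.74 kb. The P450 call did not hold in the pooled list (1.25-fold, adjusted permutation p = 0.389), with at least 500 bp under peaks (4.89-fold, adjusted permutation p = 0.0608), within 2 kb of the TSS (5.18-fold, adjusted permutation p = 0.146) or without chromosome 7 (3.35-fold, adjusted permutation p = 0.0918). It held without either replicate, at 1.89-fold without replicate 1 (adjusted permutation p = 0.00475) and 2.01-fold without replicate 2 (adjusted permutation p = 0.0076).

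Imprinted genes, expressed from 1 parental copy, held a replicated peak in 26 of 46 genes (56.5% against 11.3%, 4.98-fold, adjusted permutation p = 0.00127, two-sided rotation test). The fold was 2.21 without replicate 1, 2.17 without replicate 2 and 2.06 in the pooled list, each past the threshold. Within 2 kb of the TSS 13 of the 46 did (28.3%, 17.5-fold, adjusted permutation p = 0.00475). Neighbours shared peaks there. The strongest peak of the list lay in an intron of Peg3 on chromosome 7 at 6729280 to 6729916, with its centre 833 bp past the Peg3 TSS and at -980 bp from that of Usp29 (signal value 4.90). A peak on chromosome 6 at 4748469 to 4748784 was centred 1321 bp past the Peg10 TSS and at -1420 bp from that of Sgce (2.94). Others had their centre 75 bp past the TSS of Airn (3.90), the noncoding RNA within Igf2r, and 534 bp past that of Nap1l5 (4.20), which lies within Herc3. Trappc9, Mest and Blcap followed Peg3 in signal value, with strongest peaks of 4.69, 4.55 and 4.38. A single peak on chromosome 2 at 157559144 to 157559713 lay in an intron of Blcap and was centred at -649 bp from the TSS of Nnat.

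The germline list did not pass over gene bodies, with 7 of 30 genes against 9.11% under rotation (23.3%, 2.56-fold, adjusted permutation p = 0.0937, unadjusted permutation p = 0.0296, two-sided rotation test). Against random genes of matched length it did (2.90-fold, adjusted permutation p = 0.032), but not without replicate 1 (1.55-fold, adjusted permutation p = 0.152), without replicate 2 (1.51-fold, adjusted permutation p = 0.243) or in the pooled list (1.47-fold, adjusted permutation p = 0.165). Within 2 kb of the TSS 5 of the 30 genes held a replicated peak (16.7% against 1.65%, 10.09-fold, adjusted permutation p = 0.00475). These were Mael, Stk31, Syce1, Ddx4 and Taf7l, with signal values of 3.33, 3.68, 3.50, 1.96 and 3.50, of which the Ddx4 peak had a −log10 q of only 0.553. Stk31 and Syce1 had 0 bp of the gene body under replicate 2's own peaks, against 263 bp and 551 bp in replicate 1's. The strongest peaks in gene bodies of the list were in Tdrd1 (4.03), Stk31 (3.68), Mov10l1 (3.62) and Syce1 (3.50).

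Olfactory receptors held a replicated peak in 59 of 1093 genes (5.4% against 2.34%, 2.30-fold, adjusted permutation p = 0.181, two-sided rotation test), with the strongest in Olfr851 (4.73), Olfr77 (4.38), Olfr868 (4.20) and Olfr869 (4.20). The list passed without replicate 2 (1.89-fold, adjusted permutation p = 0.038). Against random genes of matched length, drawn without regard to the clustering of these genes, it also passed (1.75-fold, adjusted permutation p = 0.000633). It did not pass without replicate 1 (1.53-fold, adjusted permutation p = 0.157), in the pooled list (1.42-fold, adjusted permutation p = 0.171) or under the 5 other alternatives (adjusted permutation p from 0.0798 to 0.364). Defensins held one in 4 of 64 genes (4.34-fold, adjusted permutation p = 0.288), Defb33, Defb8, Defb14 and Defb7, and serpins of clades A and B in 3 of 50 (1.24-fold, adjusted permutation p = 1), Serpina1b, Serpinb6d and Serpina10. The defensin fold was 2.22 without replicate 1 and 3.22 without replicate 2. Defb8 and Serpina10 had 0 bp under replicate 2's own peaks and Defb7 had 0 bp under replicate 1's, with only 43 bp of Defb8 and 18 bp of Defb7 under replicated peaks.

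None of the remaining lists passed, among them those of cell types present in the tissue or near it. Neural progenitor and patterning genes held a replicated peak in 1 of 30, an intronic peak of Pax3 (signal value 3.08), and neuronal genes in 3 of 23, Syt1, Nefm and Nefl (adjusted permutation p = 1 for both lists, two-sided rotation test). Nefl lies within the annotated Nefm gene body, so that its peak counted for both genes, and Nefl had 0 bp under either replicate's own peaks. Genes of blood, vessel, muscle and mesenchyme held one in 3 of 35, Pdgfrb, Tek and Pecam1, and genes of H3K9 methylation and heterochromatin in 2 of 23, Setdb1 and Fam208a (adjusted permutation p = 1 for both). No replicated peak lay in the 13 glial genes, the 20 hepatocyte genes, the 39 Hox genes, the 80 ribosomal protein genes, the 32 Rhox genes or the 57 keratin-associated protein genes. Rotation placed peaks in 9.80%, 5.13%, 2.69%, 1.74%, 2.39% and 0.718% of these lists, which are too small for a 0 to pass (adjusted permutation p from 0.956 to 1).

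**Figure D4:**
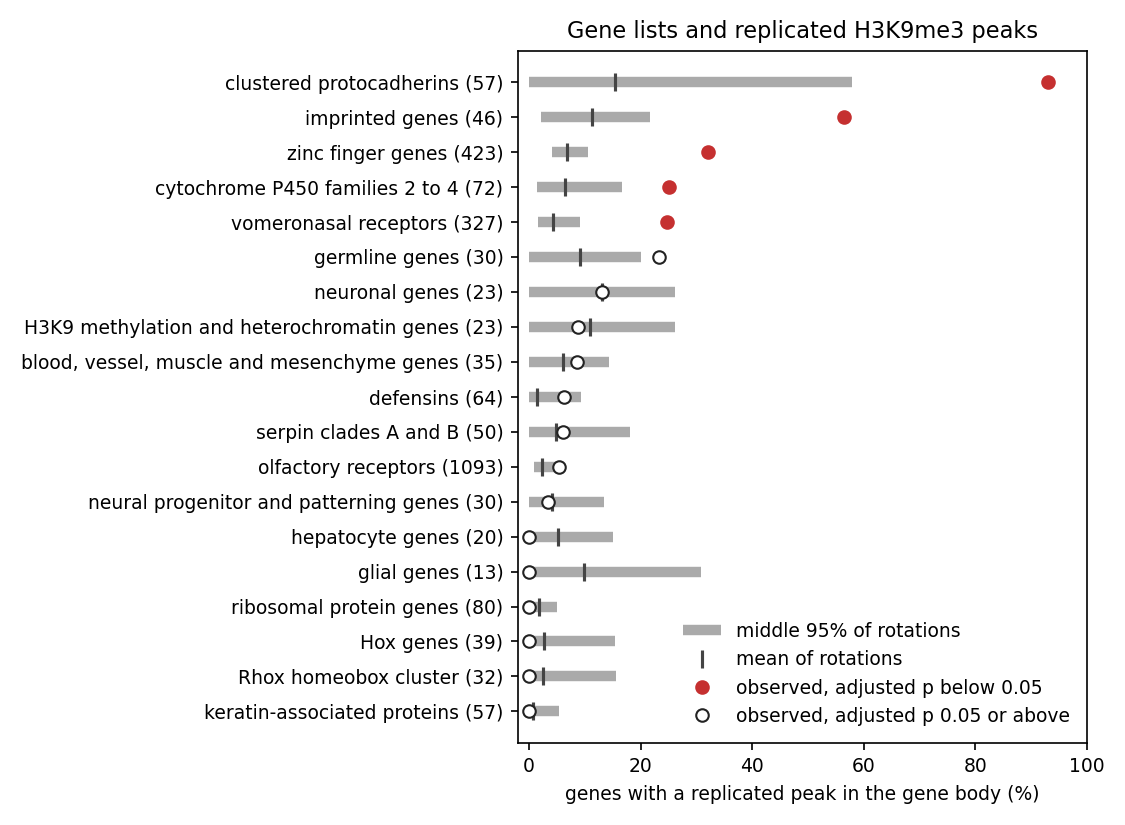
Share of the genes of each list with a replicated peak in the gene body (x axis, percent), with the number of genes in brackets; grey bars hold the middle 95% of 10000 rotations and ticks their mean. Filled points mark the 5 lists with an adjusted p below 0.05, led by clustered protocadherins at 93.0%.

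Outside the protocadherins, the genes with the most base pairs under replicated peaks were led by Skint5 (38.0 kb) and Skint6 (35.6 kb) on chromosome 4, members of a gene family expressed in skin and thymus. With overlapping gene models passed over, as chosen after the data were seen, 9 of the 25 leading genes were zinc finger genes by symbol, among them Zfp936 (17.6 kb), Zfp943 (16.1 kb) and Zfp981 (15.8 kb). The others included Mroh2a (29.7 kb, 84.1% of the gene body) and the cold-sensing channel gene Trpm8 (25 kb) on chromosome 1, the titin gene Ttn (19.8 kb), and Nlrp5 (16.2 kb), Nlrp2 (15.2 kb) and Nlrp4b (14.6 kb), of a family with members active in the egg. In Mroh2a the replicates' own lists had 28.1 kb and 26.8 kb under peaks, and in Ttn 17.0 kb and 17.4 kb. The strongest peak of Mroh2a had a signal value of 3.87 at a −log10 q of 22.0, against 3.85 at 4.48 in Trpm8. That of Zfp981 had 5.30 at 22.7, against 5.78 at 12.3 in Zfp936. A low signal value at high significance was also found on the scaffolds described below. Whether reads from copies missing in the assembly add to the Mroh2a and Zfp981 peaks was not tested.

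The strongest replicated peak by signal value (7.97) covered an exon of Klf14, a single-exon gene for a Krüppel-like transcription factor, on chromosome 6 at 30955550 to 30959263, with 88.0% of its length covered by replicate 1 and 96.4% by replicate 2. The next 2 lay in intergenic sequence on chromosome 7, at -22.8 kb and -20.5 kb from the TSS of Vmn1r77 (7.70 and 7.35). The others of the first 10 lay 111 kb downstream of the Vmn2r112 TSS on chromosome 17 (7.18), in an intron of D130040H23Rik (7.18), in Zfp110 (7.0), in the pseudogenes Gm49329 and Gm49331 on chromosome 12 (6.83), in the protocadherin cluster (6.83), in Zfp68 (6.83) and in an exon of Zfp180 (6.79).

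Replicated peaks were concentrated in few regions. The 27 densest of 2737 windows of 1 Mb, the top 1%, held 31.6% of replicated-peak base pairs, against 20.4% in replicate 1's own list and 18% in replicate 2's. The first was the protocadherin window of chromosome 18 from 37 to 38 Mb, with 221 kb under peaks. The second, chromosome 7 from 33 to 34 Mb, held 12 secretoglobin (Scgb) genes and 139 kb under peaks, and the third, chromosome 12 from 114 to 115 Mb, held 89 immunoglobulin heavy chain variable (Ighv) segments and 127 kb. The next was chromosome 7 from 17 to 18 Mb (122 kb), with 4 Ceacam and 2 Psg genes, families with placental members, followed by chromosome 13 from 61 to 62 Mb (105 kb) with 8 cathepsin (Cts) genes. Chromosome 10 from 82 to 83 Mb (94.6 kb) held Zfp873, Zfp938 and Gm4924. The windows of chromosome 7 from 10 to 11, 12 to 13 and 23 to 24 Mb held 6, 8 and 18 Vmn1r genes, with 92.0, 92.7 and 88.1 kb under peaks, and that of chromosome 4 from 121 to 122 Mb (89.8 kb) held 8 protein-coding genes.

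Joining peaks no more than 5 kb apart gave 7335 domains, of which 74.5% were a single peak. Domains of at least 10 kb numbered 349 and held 33.9% of replicated-peak base pairs, and 11 reached 50 kb. These values followed the joining distance, with 28 domains of at least 10 kb, 5.31% of base pairs and 0 of 50 kb at 1 kb, 561, 53.3% and 85 at 10 kb, and 613, 63.2% and 170 at 20 kb. Without replicate 1 there were 29177 domains, 728 of at least 10 kb and 37 of 50 kb, and without replicate 2 there were 22734, 587 and 30. Of the 10 longest domains 5 lay in the protocadherin cluster. One of 75.5 kb lay among the Ighv segments on chromosome 12, one of 64.2 kb on chromosome 4 from 121995679 to 122059844 overlapped no protein-coding gene, and one of 62.8 kb on chromosome 5 overlapped Zfp951.

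Replicated peaks were richer in G and C than rotated peaks, at 44.4% against 41.7% (rotations, 40.6% to 42.8%), and poorer in CpG, with an observed over expected ratio of 0.171 against 0.190 (0.179 to 0.199). Masked repeats made up 31.9% of their bases against 36.7% (33.1% to 47.3%). Each measure lay outside all 100 rotations (two-sided permutation p = 0.0198 for each, the smallest these rotations can give).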

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

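The tests by rotation left out the unplaced and unlocalized scaffolds, sequence of the assembly with no known position, and these held 248 replicated peaks over 229 kb. The test of their signal value was set before its result was seen, and no biological explanation was tested, since the design names none. Scaffolds carried 1.84% of the replicated peaks, against 0.526% of the pooled peaks, 0.962% of those of replicate 1 and 0.755% of those of replicate 2. Their median −log10 q was 11.1 against 3.38 on the chromosomes, and 45 of the 100 replicated peaks with the highest −log10 q lay on them. Within 10 bins of −log10 q, however, the median signal value of scaffold peaks was 0.896 times that of chromosome peaks (two-sided permutation test within bins, p = 0.001, the smallest 2000 permutations can give), although without matching it was not lower (3.43 against 3.37). A lower signal value at the same significance is consistent with reads from copies missing in the assembly piling up in both the ChIP and the control libraries. The test does not exclude that the mark itself is also high on these sequences, which stays open.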

How the results depend on the processing

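Overlap by rank, the rule for the replicated list, and lists without the protocadherin region or chromosome 7 were chosen after the data were seen. Peak sharing between replicates stayed far above rotation under all 4 other overlap rules and thresholds, from 11.3% to 30.0%. The count of 5 enriched lists was between 4 and 7 and that of depleted lists was 0 under every alternative, but the lists behind the count changed. Zinc finger genes did not pass around the TSS. P450 genes did not pass there, in the pooled list, with at least 500 bp under peaks or without chromosome 7. Germline genes entered around the TSS and olfactory receptors without replicate 2, and both entered with lists matched on gene length. The count of 7 came from random lists matched on gene length, which take no account of the clustering of gene families. The exon excess, the intron deficit and the 3 composition measures kept their direction and their side of the threshold under each alternative. The rank coefficient moved to 0.164 with 1 bp of overlap and 0.386 with −log10 q of at least 2. The share of replicated peaks recovered in both replicates moved to 80.5% with 1 bp, 51.9% with −log10 q of at least 2, and 80.0% by 50% of either peak. With pooled peaks the ratio was 2.76 on chromosome 7, 2.05 on 17, 1.39 on 4 and 0.498 on X, the promoter fold 1.01 (adjusted permutation p = 0.856), the intergenic fold 1.17 (adjusted permutation p = 0.002, now past the threshold), the share in the densest windows 19%, and the domains numbered 37343. With −log10 q of at least 2 chromosome 4 stood at 1.81. Windows of 500 kb raised the share in the densest 1% to 37.1%. Leaving out either replicate, by using the other's own list, gave 2.54 to 2.77 on chromosome 7, 1.96 to 2.12 on 17, 1.41 to 1.47 on 4 and 0.431 to 0.635 on X, promoter folds of 1.02 to 1.11 (no longer past the threshold) and intergenic folds of 1.13 to 1.14 (now past it), shares of 18% to 20.4% in the densest windows, and 22734 to 29177 domains. The zinc finger fold fell to 1.68 around the TSS (adjusted permutation p = 0.517; over its alternatives 0.000633 to 0.517), which counts a different part of the gene. The cause of the other shifts was not tested, except that longer lists of weaker peaks give more domains by construction. Unknown depth limits every statement on absent peaks.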

Other observations

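The tests of the X chromosome by 3 equal bins of −log10 q, of last exons against each gene's own shifts, and of all gene families were chosen after the results were seen; the others were set before.

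Beyond the fixed lists, 257 families of at least 10 genes sharing a symbol stem were tested for replicated peaks by rotation. After Benjamini-Hochberg adjustment 5 families had more members with a peak than rotation gave and 0 had fewer. At an unadjusted p under 0.05, 14 had more and 4 had fewer, among them Wdr genes with 0 of 64. Immunoglobulin heavy chain variable segments (Ighv) held one in 24 of 113 (21.2% against 0.466% under rotation, adjusted permutation p = 0.0128, two-sided permutation test), and Nlrp genes, several of which act in the egg, in 9 of 17 (52.9% against 9.70%, adjusted permutation p = 0.0411). The other 3 were the Zfp, Vmn and Pcdhb families, which overlap the fixed lists. Among the protocadherins with overlapping gene models, Pcdha and Pcdhga held a peak in 12 of 12 genes each but did not pass. Rotation gave 33.0% for Pcdha and 22.6% for Pcdhga (unadjusted permutation p = 0.554 and 0.305). Secretoglobins (8 of 34, adjusted permutation p = 0.109) and Ceacam genes (7 of 15, adjusted permutation p = 0.114) did not pass.

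Retroviruses start reverse transcription from a tRNA bound at a primer binding site, a stretch of 18 bases complementary to the 3' end of that tRNA. Exact matches to the sites predicted from annotated tRNA genes numbered 4158 in the genome, and 363 of them (8.73%) had a replicated peak within 5 kb, against 3.22% under rotation (2.72-fold, two-sided permutation p = 0.0002, the smallest possible). Sites for proline tRNA stood highest, with 59 of 201 near a peak (29.4% against 3.23%, 9.08-fold, adjusted permutation p = 0.00045), followed among tRNAs with over 100 sites by lysine (12.3%, 3.8-fold) and leucine (9.55%, 2.97-fold, both adjusted permutation p = 0.00045). Sites for isoleucine (1.68-fold), phenylalanine (2.13-fold), phenylalanine or serine (2.32-fold) and threonine (3.93-fold, 47 sites) also passed (adjusted permutation p from 0.00045 to 0.0116). Glutamine and glycine sites did not pass (adjusted permutation p = 0.241 and 0.191). As a hypothesis, replicated peaks may gather at endogenous retroviruses, those primed by proline tRNA most. A match of 18 bases does not show that a provirus is present, and whether the tRNAs differ from one another was not tested. Replicated peaks as a whole held fewer masked repeat bases than rotated peaks (31.9% against 36.7%), and a peak within 5 kb of a site need not lie on a repeat.

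In zinc finger genes replicated peaks covered a larger share of the last exon, which in most of them codes the finger array, than of the rest of the transcript. In 133 multi-exon genes with a peak in the longest coding transcript, peaks covered 39.2% of last-exon bases against 8.39% of the rest, a ratio of 4.67 (one-sided permutation p = 0.0001 in shifts of peaks within each gene, the smallest possible). Whether exons simply map better than introns was tested in 1220 other genes with a peak, and the test set beforehand, the pooled ratio of zinc finger over other genes, came out at 0.663 (bootstrap 95% interval, 0.456 to 0.997), the way better mapping predicts; it was set aside only after this was seen, since shifts alone gave the other genes a ratio of 4.65, against 1.37 in zinc finger genes. In the test added in its place, last-exon peak base pairs were 2.41 times the expectation from each gene's own shifts in zinc finger genes and 1.48 times in the others, a ratio of 1.63 (bootstrap 95% interval, 1.32 to 2.01). That interval lies above 1, the bound first used for the added test, but not above 2, the bound set beforehand, so better mapping of exons may account for the pattern, and a mark on the 3' exon of these genes stays an open hypothesis.

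The low density on the X was weighed against its repeats and its copy number. Autosomal windows weighted to the X's share of masked bases (46.7% against 33.5%) had 13.5 times its density of replicated peaks (bootstrap 95% interval, 7.30 to 25.8). The unweighted value was 5.06. Weighting thus raised the autosomal density, so the masked share as such did not predict the low density of the X. How well reads can be placed was not measured, so the test cannot decide whether reads lost in repeats lower the X. The X stood lower in the highest bin of −log10 q than in the lowest. From highest to lowest, its density over that of the autosomes was 0.370, 0.374 and 0.475 in replicate 1, the first 2 nearly equal, and 0.456, 0.547 and 0.873 in replicate 2, and the highest over the lowest gave 0.779 and 0.522. That is consistent with lower power on a chromosome present in fewer copies in pools of both sexes, and a lower level of the mark on the X would give the same, so the 2 stay open.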
